A study of Homo sapiens with 11 samples.

How the data were processed

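The series holds 11 libraries, 1 per group. DNase-seq, which maps chromatin open to the nuclease DNase I, was made in 16HBE14o-, a transformed human bronchial epithelial cell line. ChIP-seq for 5 histone marks (H3K4me3, H3K27me3, H3K9me2, H3K9me3 and H3K36me3) was made in Calu3, a human lung adenocarcinoma line, and in HBE, primary human bronchial epithelial cells. Each library was assigned to its group by its title.

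Reads had been aligned with Bowtie 1.0.0 to hg19 and peaks called with HOMER, given as version 1.2, per the submitters' processing notes. Each histone list was called on 1 tag directory against an input directory, with windows of 500 bp joined into regions of variable length, at least 4 times the input and a Poisson p over input of 1e-04, per the file headers. The DNase list was called without an input on a tag directory named as combined, with peaks of fixed width of 151 bp at an FDR of 0.001, per the file headers. Whether that directory pools replicates is not given in the sources used here. Several histone libraries of one cell type share an input, among them H3K9me2 and H3K9me3 of HBE, per the file headers. The deposited score of each peak is the authors' normalised tag count, in tags per 10M (M for mega) tags of the library, rounded to whole numbers. Its sum over a list differs from the header's own total by at most 0.122 per peak. These scores are the authors' and are given as tags per 10M. Approximate raw tags were obtained by multiplying a score by the library's total over 10M. From them, exact Poisson intervals at the 95% level were computed for named promoters, covering counting error only.

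The threshold in tags per window differed per library, per the file headers, so a list's length reflects depth and antibody as well as the cells. Total tags ranged from 21.4M in Calu3 H3K27me3 to 86.7M in HBE H3K27me3. The share of tags in peaks ranged from 0.52% in HBE H3K9me2 to 36.3% in Calu3 H3K4me3, per the file headers. With 1 library per group, no difference between Calu3 and HBE has a replicate check, and no p-value was computed. Only the 22 autosomes were used, because HBE cells come from a person.

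Peaks were compared by overlap of at least 1 bp. Shares carry Wilson 95% intervals over peaks. These treat peaks as independent, though neighbouring peaks can be parts of 1 marked region. They may therefore be too narrow even within a library, and they hold no error between libraries. Each pair of lists was set beside 100 circular shifts of one list along each chromosome. The shifts had no mask, so shifted peaks could fall in assembly gaps and gene-poor sequence. An excess over shifting therefore includes what any 2 lists share by lying in the same kind of sequence. Coverage of the 11p13 window, chromosome 11 from 34000001 to 36000000, was placed among 2711 autosomal windows of 2 Mb at 1 Mb steps that held a peak of any library. For the interval of a covered percent, 1 kb units of the window were taken as the counted items. The overlap code was tested on simulated data, as lists of 20000 peaks. With 0%, 30% and 60% of peaks planted in common it recovered 1.75%, 31.1% and 60.7%, against 1.69%, 1.72% and 1.73% after shifting.

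No hg19 gene annotation was used here. The planned counts of annotated promoters and covered gene bodies, with their alternatives, were therefore not run, nor was the share of DNase sites near transcript starts. Landmark windows of 1 Mb took their place, as planned for that case. For the fixed gene lists, windows of 171 genes and 13 gene clusters were set by hand from general knowledge of hg19. They were set after the lists had been opened and after the EHF, CFTR and 17q12 regions and the highest peaks of each list had been seen. In a gene table of GRCh38.p14, all 171 genes lay on the same chromosome and 150 of 150 neighbouring pairs lay in the same order. No coordinate was taken from that table. Members of the lists without a window, the ETS family list and the tumour suppressor list were not analysed here. H3K4me3 was counted at a locus when a peak lay within 1 kb of its window. Other marks were given as the percent of the window covered. Counts were set beside 10000 sets of random windows of the same lengths. These random windows are not genes, so they describe the background density of peaks only.

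The rule for named items was fixed before the data were examined: all genes of the 11p13 window, the 12 highest H3K4me3 peaks each way with none within 5 kb in the other cell type, the 10 highest peaks each way with opposite marks, the ranked 1 Mb windows and examples from each list. At ranked peaks, 19 further genes were named only where their place in hg19 was known without an annotation. Those names were set after the peaks had been seen, and unnamed peaks are given by position. Beyond 2 to 4 members per list, list members named were chosen after their values were seen. The parts of the rule that rank gene bodies were not run, and some items the rule picks are not given here, though counts include them. The rule as fixed ranked annotated promoters; H3K4me3 peaks stood in for them in both rankings, a choice made after the data were seen.

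To follow differences in DNA copy number, shared H3K4me3 peaks of at least 20 tags per 10M in both lists that matched 1 to 1 were used. The median Calu3 to HBE ratio of their tags was taken in 245 bins of 10 Mb with at least 20 such peaks, leaving out 17q12. Alternatives were the better-scored 50% of each list, the share also used for stricter overlap, lists of equal covered length, joining of peaks under 1 kb apart, a shorter 11p13 window and wider promoter flanks. Bins of middling tag ratio and the removal of 17q12 were added after the data were seen. Computations used Python 3.11.15, NumPy 2.4.6 and SciPy 1.17.1, and figures used matplotlib 3.10.9.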

Results

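The data describe open chromatin in 16HBE14o- cells and 5 histone marks in Calu3 and HBE cells. H3K4me3 marks promoters, H3K36me3 the bodies of transcribed genes, H3K27me3 Polycomb-repressed regions, and H3K9me2 and H3K9me3 heterochromatin. The autosomal lists held 69788 DNase sites, 23717 H3K4me3 peaks in Calu3 and 21100 in HBE, and 83044 and 54921 H3K27me3 peaks. They held 64903 H3K36me3 peaks in Calu3 and 99933 in HBE, 46567 and 43891 H3K9me3 peaks, and 42679 and 10042 H3K9me2 peaks. In total tags, the DNase library held 33.6M. For H3K4me3, Calu3 and HBE held 23.3 and 34.3M, for H3K27me3 21.4 and 86.7M, and for H3K36me3 50.6 and 40.8M. For H3K9me2 they held 55.1 and 67.1M, and for H3K9me3 47.9 and 28.7M. Each group is 1 library, so no difference below has a replicate check.

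The series was designed to find regulatory elements at 11p13, a region that modifies lung disease in cystic fibrosis. EHF, an epithelial ETS transcription factor, carried a broad H3K4me3 peak at its start in both cell types. It spanned 34641578 to 34647745 on chromosome 11 in Calu3 with 522 tags per 10M (95% Poisson interval 493 to 552) and 34642111 to 34648940 in HBE with 606 (580 to 633). H3K36me3 covered 23.5% of the EHF window in Calu3 and 17% in HBE, and H3K27me3 covered 1.88% and 7.44%. The Calu3 H3K27me3 came from a single peak, from 34641236 to 34642807, nearly at the place of a high H3K9me2 peak of HBE taken up below. ELF5, the neighbouring ETS factor gene, had no H3K4me3 peak in either cell type. The start shared by APIP and PDHX carried 363 tags per 10M in Calu3 (339 to 388) and 283 in HBE (266 to 301), and a DNase site of 16HBE14o- began within it at 34938085. CD44, a cell adhesion receptor, carried 650 (618 to 684) and 393 (372 to 415), with 41.2% and 20.5% of its window under H3K36me3.

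Among the other genes of the window, ABTB2 had H3K4me3 peaks summing to 691 tags per 10M in Calu3 and 193 in HBE, and H3K36me3 over 11.8% and 0.548% of it. CAPRIN1, NAT10, CAT, FJX1 and TRIM44 carried H3K4me3 in both, with CAPRIN1 at 516 and 433 and CAT at 192 and 191. SLC1A2, a glutamate transporter gene, had 196 and 59. Its highest H3K4me3 peak in each cell type, of 159 and 59, lay within the highest H3K27me3 peak of the 11p13 window. That H3K27me3 peak had 187 tags per 10M in Calu3 and 100 in HBE. PAMR1 had an H3K4me3 peak of 30 in Calu3 alone, and H3K27me3 covered 33.0% of PAMR1 in Calu3 and 7.0% in HBE. No DNase site of 16HBE14o- lay within 1 kb of the EHF window. Sites upstream of it began at 34586148 and 34592179.

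Over the whole 2 Mb, H3K4me3 covered 2.94% in Calu3 (percentile 87.2 of autosomal windows) and 2.14% in HBE (80.1). H3K36me3 covered 7.33% (93.2) and 5.23% (71.0), H3K27me3 4.41% (75.7) and 2.01% (69.6), and H3K9me3 1.04% (62.4) and 0.632% (61.3). DNase sites covered 0.362% (54.1). H3K9me2 covered 1.27% in Calu3 (73.1) and 1.07% in HBE (99.98). The 4 highest H3K9me2 peaks of HBE among all autosomes lay here, at 28 to 75 tags per 10M against 14 for the next. The sign of the H3K27me3 difference between the cell types turned when the window was shortened to 34000001 to 35000000, and that of H3K9me2 turned there and with equal covered lengths.

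**Figure D1:**
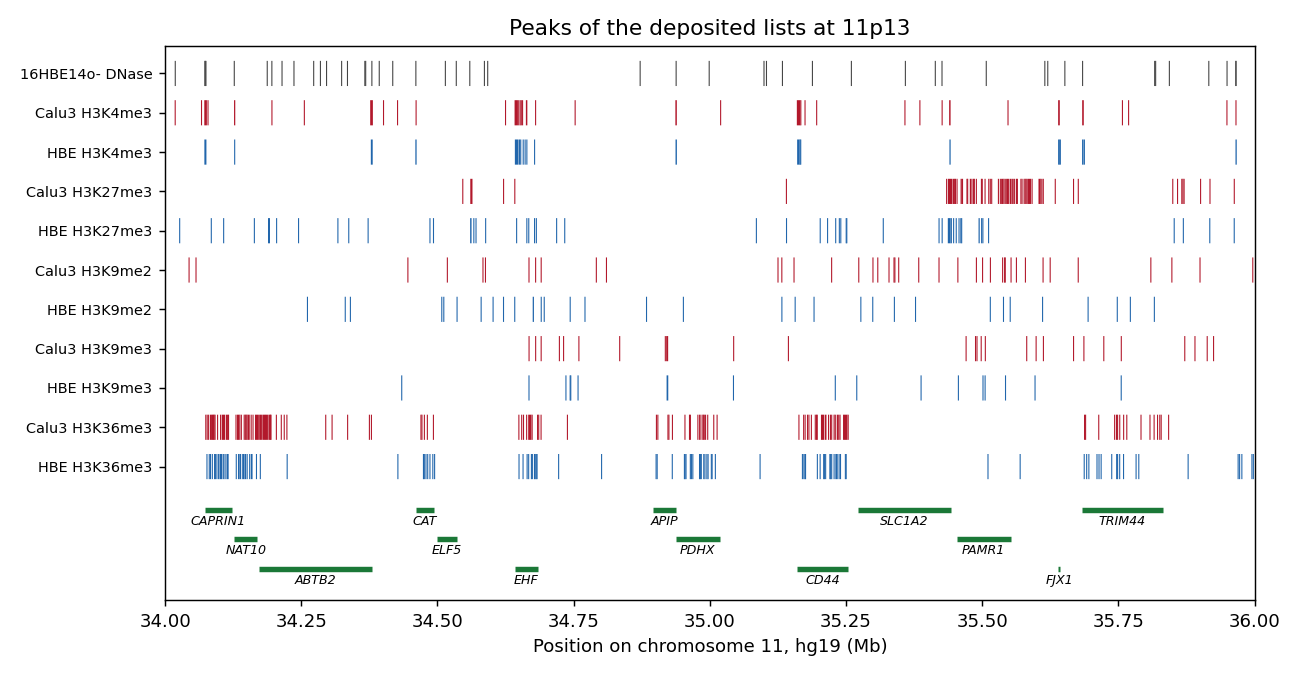
Peaks of the 11 lists (rows) along chromosome 11 in hg19 (horizontal axis, Mb), each drawn at least 2 kb wide so that none is lost, with hand-set gene windows in green. H3K4me3 peaks stand at the start of EHF in Calu3 (522 tags per 10M) and HBE (606), where the DNase row is empty.

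How far Calu3 and HBE share marked regions differed by mark. H3K4me3 was shared most: 75.2% of HBE peaks (95% interval 74.6 to 75.8) met a Calu3 peak, against 3.49% on average after shifting, and 66.7% of Calu3 peaks met an HBE peak. By the share of HBE peaks in the lists as deposited H3K9me3 followed, with 35.2% (34.8 to 35.7) of peaks of the library labelled HBE H3K9me3 against 4.36%. Covered length in that library followed the Calu3 to HBE tag ratio over 10 Mb bins with a Spearman rho of 0.80, across bins that are not independent replicates, so this share is not a plain comparison of cell types. H3K27me3 reached 25.8% (25.5 to 26.2) against 6.03%, and H3K36me3 25.1% (24.8 to 25.3) against 4.80%. H3K9me2 was shared least, at 7.17% (6.68 to 7.69) against 1.83%. Of Calu3 peaks, 39.5% met an HBE peak for H3K36me3, 33.4% for H3K9me3, 16.6% for H3K27me3 and 1.69% for H3K9me2. In that direction H3K36me3 stood second, and well apart from H3K27me3. In length, 31.2 Mb of H3K4me3 was shared, 11.8 Mb of H3K27me3, 16.5 Mb of H3K36me3, 13.7 Mb of H3K9me3 and 0.243 Mb of H3K9me2. Each of the 5 shares of HBE peaks lay above the highest of its 100 shifts, which had no mask for gaps or gene-poor sequence. The H3K27me3, H3K9me2, H3K9me3 and H3K36me3 shares of HBE peaks moved by over 1.5 times when 50% of both peaks had to overlap, to 6.84%, 3.52%, 17.4% and 4.55%. With equal covered lengths the H3K27me3, H3K9me2 and H3K36me3 shares moved as much, to 13.5%, 1.42% and 42.2%; H3K36me3 then stood above H3K9me3, at 37.2%.

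**Figure D2:**
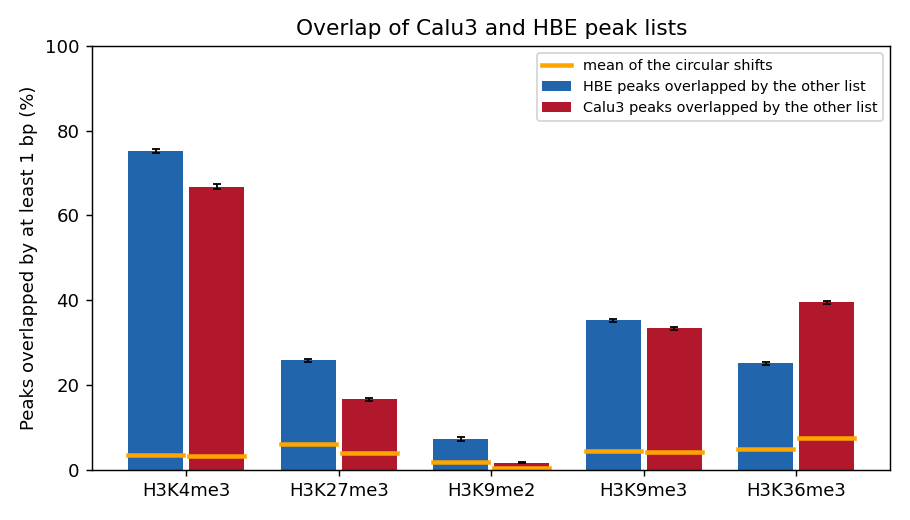
Percent of peaks (vertical axis) overlapped by at least 1 bp in the list of the same mark of the other cell type, for HBE peaks (blue) and Calu3 peaks (red), with Wilson 95% intervals as bars and the mean of 100 circular shifts as orange lines. H3K4me3 reached 75.2% and 66.7%, and H3K9me2 7.17% and 1.69%.

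H3K4me3 peaks found in one cell type with none within 5 kb in the other numbered 6454 in Calu3 (27.2%) and 3972 in HBE (18.8%). Most were low: their median was 13 tags per 10M in Calu3 and 9 in HBE, against 89 and 97 over all peaks, and 164 and 170 of them reached 100. The highest in Calu3 included ARL14 (609 tags per 10M), KIF1A (530), TM4SF4 (515), HNF4A (477), a nuclear factor of liver and gut, HKDC1 (470), GATA4 (383), GRIN2A (378) and NPC1L1 (356), an intestinal cholesterol transporter. PPP1R1B stood first with 1082, but it lies inside the 17q12 segment where Calu3 tags are raised throughout. The median Calu3 to HBE tag ratio of the 10 Mb bin, which bears on a ranking by tags, was also high at ARL14 (2.84), HNF4A (1.95), NPC1L1 (1.91) and TM4SF4 (1.85), and was 1.22 at KIF1A and 1.17 at GRIN2A. The highest in HBE included KRT5 (410), the keratin of airway basal cells, TP63 (377), their master transcription factor, MIR205HG (468) and SCNN1A (419), a subunit of the epithelial sodium channel. FLRT2 (717), TNS4 (639), IRX2 (570), TSHZ3 (495), BNC1 (445) and CDH11 (377) were also among them. The ranking is of peaks, not genes: Calu3 had an H3K4me3 peak elsewhere at SCNN1A (100) and at TP63 (10). Peaks of the ranking without a name began in Calu3 at 64657446 on chromosome 11 (422) and 86123768 on chromosome 15 (359), and in HBE at 124194536 on chromosome 8 (433) and 31644028 on chromosome 22 (414).

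Opposite marks, H3K4me3 without H3K27me3 in one cell type and H3K27me3 without H3K4me3 in the other, were found at 364 Calu3 peaks and 215 HBE peaks. These were 4.81% of 7568 and 4.40% of 4887 H3K4me3 peaks with none within 1 kb in the other cell type. An overlap of 1 bp was enough, and no shifted lists were run. Shifted DNase sites, which are narrower, met H3K27me3 of HBE at 2.22% and of Calu3 at 3.86%. Whether the counts exceed chance placement was therefore not tested. H3K27me3 covered 83.4% of the HNF4A peak but 8.83% of the BNC1 peak. The highest in Calu3 included HNF4A (477 tags per 10M), GRIN2A (378), SERPINA3 (344), a peak inside the HOXB cluster (336), MUC5AC (333), which encodes the gel-forming mucin of goblet cells, and USH1C (271). In HBE they included BNC1 (445), a transcription factor of keratinocytes, SEMA5A (304), NLRP1 (173) and a peak beside NKX2-1 (92), the lung and thyroid factor. The unnamed ones in Calu3 began at 39866953 on chromosome 22, 31060159 on chromosome 20 and 37245356 on chromosome 4. Those in HBE began at 121967863 on chromosome 11, 55600152 and 58018346 on chromosome 16, 36977218 on chromosome 14, 32167916 on chromosome 1 and 39692596 on chromosome 6. H3K4me3 and H3K27me3 of the same cell type met at 3228 Calu3 peaks (13.6%) and 4740 HBE peaks (22.5%). The HBE count of opposite marks was 52 in the better-scored 50% of each list and 105 with equal covered lengths.

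Among the fixed gene lists, H3K4me3 counts differed by 4 or more loci between the cell types for the airway basal, squamous and developmental lists. Of 16 airway basal loci, 15 carried H3K4me3 in HBE and 11 in Calu3, and 4 did so in HBE alone: KRT5 (410 tags per 10M), COL17A1 (291), KRT6A (173) and KRT14 (58). TRIM29 had 747 in HBE and 37 in Calu3, TP63 384 and 10, and S100A2 347 and 26. H3K36me3 coverage was at least 10 points higher in HBE at 8 basal loci and in Calu3 at 1, and H3K27me3 coverage was so in HBE at 6, with LAMB3 at 20.7% and KRT5 at 17.7%, and in Calu3 at 1. Of 14 squamous loci, 7 carried H3K4me3 in HBE and 1, KRT10, in Calu3; the 6 marked in HBE alone included SERPINB13 (114), TGM1 (92) and SPRR1B (69), and the other 3 had few tags, IVL 7, FLG 8 and KRT16 9.

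Airway secretory loci carried H3K4me3 at 10 of 17 in each cell type. MUC5AC had 333 tags per 10M in Calu3 and no peak in HBE, AGR2 431 and 44, MUC5B 198 and 25, and FOXA3 818 and 225. The tag ratio of the 10 Mb bin was 2.37 at AGR2, 1.55 at FOXA3 and 1.24 at MUC5AC and MUC5B. SLPI had 148 and 124 and LTF 13 and 9, while MSLN had 41 in Calu3 and 83 in HBE, and CEACAM6 was marked in HBE alone (17). H3K36me3 covered 31.8% of MUC5B and 26.6% of MUC5AC in Calu3 and none of either in HBE. At the 15 housekeeping loci taken up below, H3K36me3 coverage was at least 10 points higher in Calu3 at 7 and in HBE at 3. GAPDH had 64.3% in Calu3 and 10.0% in HBE, and POLR2A 21.8% and 49.6%. A difference in H3K36me3 coverage at a locus therefore does not by itself show a difference in transcription. SCGB1A1, the club cell secretoglobin, had no H3K4me3 peak in either. Of 5 ciliated loci, 5 carried H3K4me3 in Calu3 and 3 in HBE; FOXJ1, the factor of motile cilia, had 43 and 44 tags per 10M, with H3K27me3 over 72.9% of it in HBE and none in Calu3.

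Epithelial transcription factor loci carried H3K4me3 at 17 of 18 in Calu3 and 14 in HBE. HNF4A and CDX2 were among those marked in Calu3 alone (512 and 176 tags per 10M); the tag ratio of the 10 Mb bin was 1.95 at HNF4A and 0.816 at CDX2. ELF3 had 976 in Calu3 and 41 in HBE, with H3K36me3 over 52.3% of ELF3 in Calu3 and none in HBE. KLF5 (308 and 705), SOX2 (160 and 366), NKX2-1 (171 and 610) and GRHL3 (97 and 291) had more tags in HBE, though at KLF5 the bin as a whole leaned at least as far towards HBE. GRHL2 (388 and 421) and TFAP2A (1002 and 1055) were close. Of 10 junction loci, 10 were marked in Calu3 and 8 in HBE; CLDN3 had 192 in Calu3 and none in HBE, where H3K27me3 covered 62.5% of it, while CLDN7 had 377 and 386.

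Ion transport loci were marked at 11 of 12 in Calu3 and 12 of 12 in HBE. CFTR, the chloride channel mutated in cystic fibrosis, carried 323 tags per 10M in Calu3 (95% Poisson interval 300.2 to 347) and 89 in HBE (79.3 to 99.6), with H3K36me3 over 14.1% of it in Calu3 and none in HBE. SCNN1A had 100 and 458 and AQP3 55 and 210. AQP5 had 160 and 23, with H3K27me3 over 48.5% of it in HBE.

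Among loci of other cell types, mesenchymal ones carried H3K4me3 at 11 of 13 in Calu3 and 9 in HBE, with SNAI2 at 46 and 563 and VIM at 437 and 251. COL1A2 and COL3A1 had none in either. Immune loci were marked at 4 of 10 in each, and PTPRC, CD3E and MS4A1 had no peak. Endothelial loci were marked at 2 of 4 in Calu3 and 1 in HBE, and CDH5 and TEK had none. All 15 housekeeping and 5 cell cycle loci carried H3K4me3 in both, against 1.68 and 0.841 in random windows of the same lengths in Calu3. In Calu3 and HBE, such windows gave 3.49 and 3.28 for the mesenchymal list and 2.03 and 1.87 for the immune list. They gave 1.63 and 1.53 for the endothelial list and 1.26 and 1.15 for the squamous list. The endothelial counts and the squamous count of Calu3 were thus near this background.

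H3K27me3 covered 85.7% of the HOXA cluster in HBE and 8.37% in Calu3, 62.9% and 2.13% of HOXB, 92.1% and 53.1% of HOXC, and 81.0% and 22% of HOXD. H3K4me3 peaks summed in Calu3 and HBE to 2613 and 1325 tags per 10M at HOXA, 3141 and 562 at HOXB, 670 and 251 at HOXC, and 337 and 602 at HOXD. The median Calu3 to HBE tag ratio of shared peaks in the 10 Mb bin was 2.20 at HOXA, 1.25 at HOXB, 1.04 at HOXC and 1.21 at HOXD. At HOXA the bin thus also leaned towards Calu3. That bin takes in matched peaks of the cluster itself, and its ratio is a median over peaks, not a ratio of sums. It therefore cannot tell whether the Calu3 sum at HOXA was raised beyond its surroundings. Of 21 other developmental loci, 12 had H3K27me3 coverage at least 10 points higher in HBE and 0 in Calu3, and 17 carried H3K4me3 in Calu3 and 21 in HBE. GATA2 had 87.9% in HBE and 10.0% in Calu3, and NKX2-2 100% and none. Of the epithelial transcription factor list, 6 were at least 10 points higher in HBE, with FOXA2 at 90.6% and none in Calu3, and 2 in Calu3, with SOX2 at 42.4% and NKX2-1 at 53.6% and none in HBE. The tag ratio of the 10 Mb bin was 0.415 at NKX2-2 and FOXA2 and 2.41 at SOX2, in the direction of the coverage. It was 2.06 at GATA2, against that direction, and 1.10 at NKX2-1. H3K27me3 peaks of HBE also covered housekeeping loci, with 58.1% of ACTB, 35.9% of EEF1A1 and 26.9% of GAPDH and none of these in Calu3, and 7 of the 15 were at least 10 points higher in HBE. HBE coverage at least 10 points higher than in Calu3 therefore also occurs at active genes. It was not confined to short loci. In HBE, the longer LAMB3 window had H3K27me3 over 20.7% and H3K36me3 over 44.7%, and ITGB4 and GRHL3 also carried both marks. Across the HBE lists these marks met over 6.84% of H3K27me3 length, against 4.28% after shifting. Counts of loci higher in HBE therefore do not by themselves show repression.

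**Figure D3:**
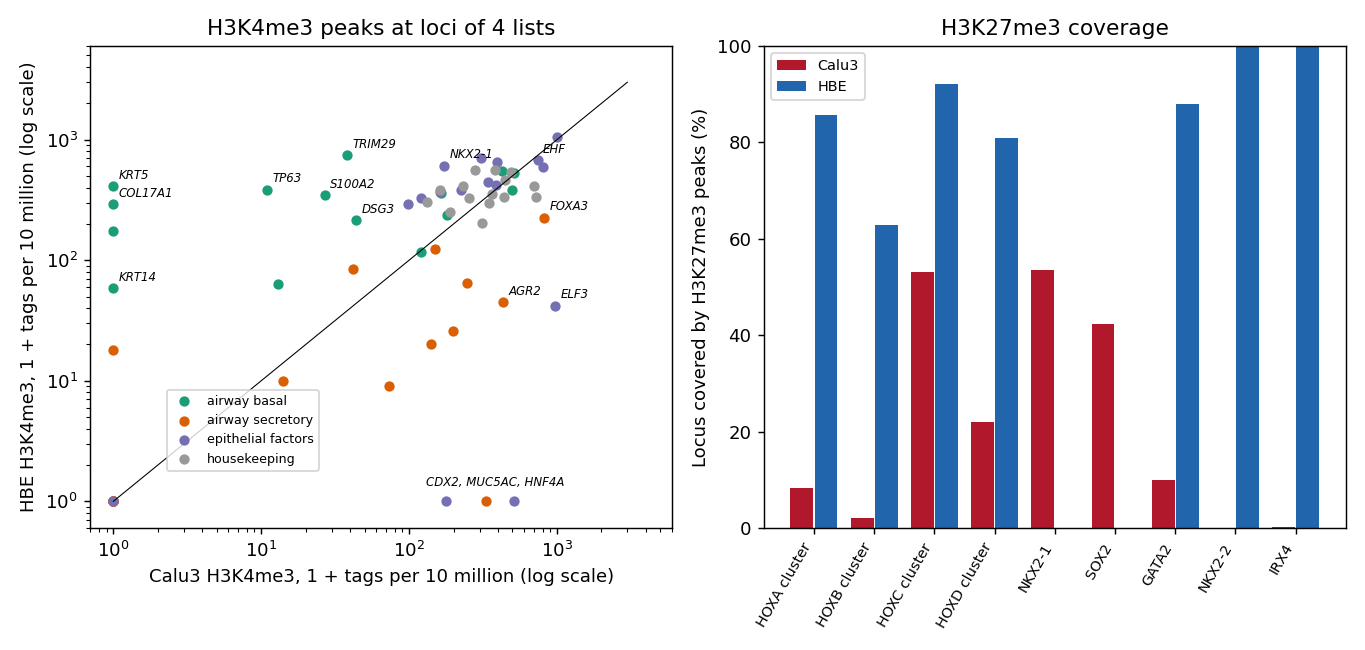
Left, H3K4me3 of Calu3 (horizontal axis) and HBE (vertical axis) as 1 + tags per 10M on log scales, 1 point per plotted locus of 4 lists, with the line of equal values. Right, percent of each locus covered by H3K27me3 peaks in Calu3 (red) and HBE (blue). KRT5 has 410 tags per 10M in HBE and none in Calu3, and the HOXB cluster is covered by 62.9% in HBE and 2.13% in Calu3.

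The 1 Mb windows with the broadest differences lay at different places for each mark. H3K27me3 was higher in Calu3 on chromosome 1 from 37000001 (56.5% covered against 3.40%, the higher cell type first for each window), chromosome 5 from 168000001 (50.8% and 1.98%), chromosome 3 from 134000001 (44.7% and 2.28%) and chromosome 12 from 5000001 (48.3% and 6.38%). In HBE it was higher at the windows of HOXB, on chromosome 17 from 46000001 (18.1% against 1.78%), and HOXA, on chromosome 7 from 27000001 (14.3% and 3.02%). H3K36me3 was higher in HBE on chromosome 15 from 41000001 (21.7% and 0.0501%) and in Calu3 on chromosome 8 from 144000001 (20.5% and 5.55%). H3K9me2 was higher in Calu3 on chromosome 3 from 134000001 (17.8% and 0.150%) and in HBE on chromosome 15 from 39000001 (0.705% and 0%). H3K4me3 was higher in Calu3 on chromosome 9 from 21000001 (7.82% and 3.55%) and in HBE on chromosome 19 from 58000001 (12.4% and 7.98%). The median Calu3 to HBE H3K4me3 tag ratio of the 10 Mb bin went with the direction at several of these windows. It was 0.395 at chromosome 15 from 41000001, 0.417 at chromosome 15 from 39000001, 2.11 at chromosome 8 from 144000001 and 2.27 at chromosome 3 from 134000001. It was 1.16 at chromosome 1 from 37000001, 1.21 at chromosome 12 from 5000001 and 1.25 at the HOXB window, and it was 2.20 at the HOXA window and 1.39 at chromosome 19 from 58000001, both higher in HBE. The windows of chromosomes 5 and 9 had no ratio.

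H3K9me3 was dense at the zinc finger genes of 19q13.4 in both lists, over 29.6% in Calu3 and 29.8% in the library labelled HBE H3K9me3, where H3K36me3 also covered 10.4% and 11.3%. It covered 21.2% and 26.6% of the clustered protocadherins. The library labelled HBE H3K9me3 differed most from Calu3 on chromosome 17 from 38000001 (58.6% against 0%) and chromosome 8 from 34000001 (57.1% and 2.71%). The first of these holds the end of a single peak at 17q12, from 37756223 to 38168031, of 412 kb and 28633 tags per 10M. This peak ends early in the window, so most of the 58.6% lies in other peaks of the library. Among the places these covered was TOP2A, beyond the end of the 412 kb peak, at 35.6%. By general knowledge of hg19 the 412 kb peak includes ERBB2, a growth factor receptor gene, named after the peak was seen. Calu3 H3K9me3 covered 0% of this segment and HBE H3K9me2 0.243%. Across 13 shared H3K4me3 peaks inside it the median Calu3 to HBE tag ratio was 31.1, against 4.15 at 35 peaks outside it within 1 Mb and 1.13 over the autosomes.

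**Figure D4:**
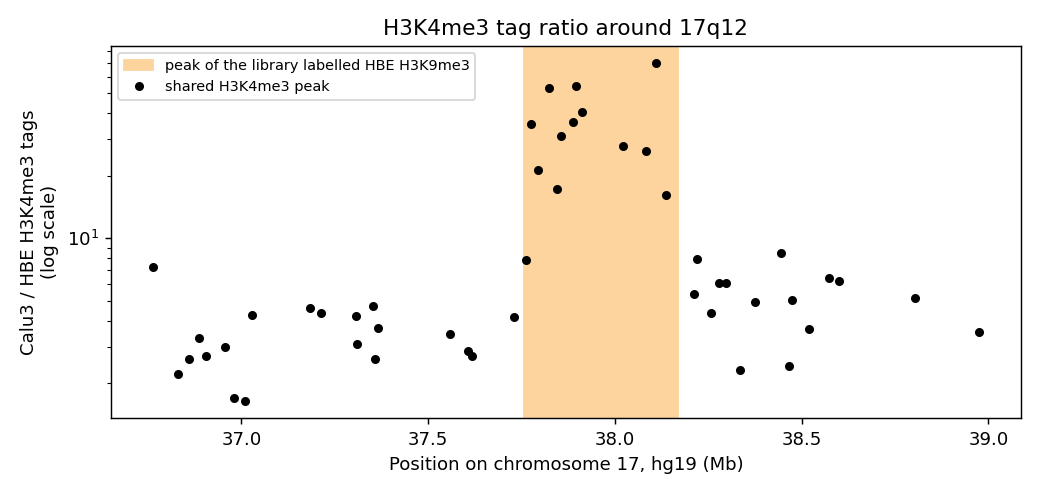
Calu3 to HBE ratio of H3K4me3 tags per 10M at shared peaks (vertical axis, log scale) along chromosome 17 in hg19 (horizontal axis, Mb), with the peak of the library labelled HBE H3K9me3 shaded. The median ratio is 31.1 inside and 4.15 outside.

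Within each cell type, marks met or avoided each other to different degrees. In Calu3, H3K27me3 and H3K36me3 met over 0.151% of H3K27me3 length, against 2.67% after shifting, while in HBE they met over 6.84% against 4.28%. H3K4me3 met H3K27me3 over 11.7% of its length in HBE against 2.01% and over 6.06% in Calu3 against 3.52%. In the better-scored 50% of each list this excess over shifting went from 0.78 to 0.12 on the log2 scale in Calu3 and from 2.54 to 1.5 in HBE. That of H3K27me3 with H3K36me3 in HBE went from 0.68 to 0.33. H3K9me2 and H3K9me3 met over 15.1% of H3K9me2 length in Calu3 against 1.80%, and over 3.60% against 1.5% with the library labelled HBE H3K9me3. H3K27me3 and H3K9me2 met over 6.53% of H3K27me3 length in Calu3 against 1.20%, and 0.417% in HBE against 0.184%. H3K4me3 met H3K9me3 over 0.627% in Calu3 against 1.71%, and over 1.86% with the library labelled HBE H3K9me3 against 1.81%, a difference whose sign turned in the better-scored 50% and after joining.

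Open sites of 16HBE14o- lay under H3K4me3 of both cell types to a like extent: 30.6% (95% interval 30.2 to 30.9) under Calu3 peaks, against 1.75% after shifting, and 29.6% (29.2 to 29.9) under HBE peaks, against 1.68%. Of all sites, 27.1% met both, 3.46% Calu3 alone, 2.44% HBE alone and 67.0% neither. The sites under both had a median of 11 tags per 10M, and those under neither 7. H3K36me3 of HBE held 1.18% of the sites against 4.67% after shifting, and H3K36me3 of Calu3 2.5% against 2.83%. H3K27me3 of HBE held 4.08% against 2.22%, and that of Calu3 3.40% against 3.86%. H3K9me3 held 1.01% in Calu3 against 1.77% and 0.974% in the library labelled HBE H3K9me3 against 1.86%. H3K9me2 held 0.470% in Calu3 against 1.15% and 0.162% in HBE against 0.237%. The sites come from another cell line, so this compares cell types as well as assays.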

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

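Each alternative changed 1 choice. Bins of middling tag ratio and the removal of 17q12 were chosen after seeing the data; the other settings were planned. Removing 17q12 left each of the 5 HBE overlap shares within its interval. It takes out only a small part of 1 chromosome, so it could hardly move a share over all autosomes. It does not bear on the rest of the library labelled HBE H3K9me3. The shares of H3K4me3, H3K27me3, H3K9me2, H3K9me3 and H3K36me3 became, in that order, 66.9%, 6.84%, 3.52%, 17.4% and 4.55% with 50% of both peaks overlapped, and 92.9%, 26.8%, 5.82%, 41.5% and 24.1% in the better-scored 50% of each list. They became 73.9%, 13.5%, 1.42%, 37.2% and 42.2% with equal covered lengths, and 77.1%, 27.1%, 8.27%, 42.5% and 27.4% in bins of middling tag ratio. Joining peaks under 1 kb apart gave 76.1% for H3K4me3, 36.3% for H3K9me3 and 26.6% for H3K36me3. At 11p13, Calu3 minus HBE coverage for H3K27me3 was 2.40 points, -0.878 in the shorter window and 0.908 with equal covered lengths. For H3K9me2 it was 0.2 points, -0.606 in the shorter window and -0.906 with equal lengths, and for H3K36me3 it was 4.42 with equal lengths. DNase coverage there was 0.0906% in the better-scored 50%. Requiring 50% of each DNase site to be covered gave 29.8% under Calu3 H3K4me3 and 28.8% under HBE H3K4me3, 3.01% and 3.64% for H3K27me3, 0.395% and 0.1003% for H3K9me2, 0.901% and 0.863% for H3K9me3, and 1.98% and 0.926% for H3K36me3. The better-scored 50% of each list gave 33.0% and 30.5%, 2.38% and 3.13%, 0.218% and 0.0659%, 0.673% and 0.585%, and 1.48% and 0.570% in the same order. Opposite marks at HBE peaks numbered 52 in the better-scored 50% of each list and 105 with equal lengths, and endothelial loci with H3K4me3 in HBE numbered 2 with a 2 kb flank. The overlap of H3K4me3 with the library labelled HBE H3K9me3, 0.04 on the log2 scale over shifting, became -0.85 in the better-scored 50% of each list and -0.0034 after joining. Halving and trimming shorten the lists, which changes overlap by construction; beyond that the cause was not tested. Promoter and gene body counts and their alternatives were not run without an hg19 annotation. No paired analysis was possible because each group holds 1 library. H3K9me2 of HBE had the lowest share of tags in peaks of the 11 libraries, 0.52%, which limits what its list can show.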

Other observations

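The tests of 17q12 inside the segment, of a low input, of heterochromatin and of both explanations at 11p13 were chosen after the result they bear on was seen. Those of tag ratios over 10 Mb bins were written before their values were computed, though peak counts per chromosome had prompted them.

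The olfactory receptor cluster of 11p15 carried H3K27me3 over 15.3% in Calu3 and 0.490% in HBE, and H3K9me2 over 3.50% and 0.195%. The zinc finger genes of 19p12 carried H3K36me3 over 7.92% in HBE and 0.340% in Calu3, with H3K4me3 peaks summing to 3637 and 1390 tags per 10M. The epidermal differentiation complex carried H3K27me3 over 16.7% in Calu3 and 4.36% in HBE. H3K4me3 peaks of the MHC class II region summed to 2098 tags per 10M in HBE and 1272 in Calu3.

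The library labelled HBE H3K9me3 held a single peak of 412 kb at 17q12. The values argue against a lack of input reads. The library's own tags per kb in the segment were 13.9 times their genome mean, which a low input would not raise. A heterochromatin domain would predict low coverage by H3K4me3 and H3K36me3 of HBE. They covered the segment more than they covered 98.6% and 90.1% of windows of that length, in that order, which went against it. This does not exclude H3K9me3 there. In Calu3, H3K9me3 met H3K36me3 over 7.37% of its length, against 3.14% after shifting. DNA of Calu3 cells in this library is a candidate explanation: the median H3K4me3 tag ratio was 7.49 times higher inside the segment than outside, and the segment of ratios above 10 ended within 29.2 kb of the peak's ends. Peaks of this library also lay beyond the segment, over 35.6% of TOP2A, where a shared H3K4me3 peak had a ratio of 6.43. Over 245 bins outside 17q12, covered length in this library followed the Calu3 to HBE tag ratio with a Spearman rho of 0.80, against at most 0.14 for the other HBE lists and 0.69 for Calu3 H3K9me3, which suggests that the whole library may hold Calu3 DNA called against an HBE input. Calu3 H3K9me3 follows the ratio too, so a swap between these libraries lacks its partner, and whether a wrong label or a mixture is the source stays open.

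The 4 highest H3K9me2 peaks of HBE all lay at 11p13, from 34674849 (75 tags per 10M), 34640971 (72), 34620728 (38) and 34535352 (28), while the next in the list reached 14. Whether cloned or amplified DNA of the locus is the source stays open: 2 of the 4 intervals also held a peak of another mark in Calu3, but 1 of these is the start of EHF, where H3K4me3 was present in both cell types. That interval, from 34640971, also met a Calu3 H3K27me3 peak from 34641236 to 34642807. This peak had 85 tags per 10M, against a median of 11 in its list. Of all Calu3 H3K4me3 peaks, 13.6% met H3K27me3 of Calu3, and whether this peak has another source was not tested. Of the other 3 intervals, only that from 34620728 held a peak of another mark in Calu3, a low H3K27me3 peak of 13 tags per 10M. Of the list's other peaks away from H3K4me3, 14.6% did so, and 3 intervals are too few to decide. Coverage outside these peaks in the 0.2 Mb around ELF5 and EHF, 1.63%, exceeded 99.8% of windows of that length. It came from narrow calls of 4 to 7 tags per 10M, near the list's threshold of 32 raw tags. The window was also set after the peaks were seen. Extra DNA of the locus could raise such calls too. This coverage therefore cannot tell a domain of H3K9me2 in HBE from locus DNA, and a domain stays open as well. High H3K9me2 peaks at EHF were not confined to HBE. Calu3 had narrow ones from 34679700 (28 tags per 10M, rank 302 of 42679) and 34667741 (24, rank 518), outside the 4 HBE intervals. These met Calu3 H3K9me3 peaks of 18 and 17 tags per 10M. The second also met a peak of 18 in the library labelled HBE H3K9me3. Their source was not tested.

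Chromosomes differed in covered length between the Calu3 and HBE lists, and the median H3K4me3 tag ratio ran from 0.704 on chromosome 13 to 1.65 on chromosome 20. Copy number of the Calu3 genome is a candidate explanation: over 10 Mb bins the Calu3 to HBE ratio of covered length followed the tag ratio with a rho of 0.62 to 0.79 for H3K27me3, H3K36me3 and H3K9me2. For H3K9me3 the rho was -0.66. There the divisor is the library labelled HBE H3K9me3, the one in doubt above. Its own covered length followed the tag ratio with a rho of 0.80, against 0.69 for Calu3 H3K9me3. No biological explanation was tested for this pattern.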
